A study of Arabidopsis thaliana with 10 samples.

How the data were processed

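Total RNA from vegetative shoot apices of Arabidopsis thaliana was hybridised to Affymetrix expression arrays, 1 array per sample. The 10 arrays fell into 5 groups of 2 according to the sample labels. Per the labels' protocols, plants were grown on soil at 20 °C with 10 h of light, RNA was extracted with a Qiagen RNeasy kit, and labelling followed the standard Affymetrix protocol. Each value deposited by the authors is the intensity of a probe set on a linear scale, made with MAS5 per the submitters' processing notes. The version of MAS5, its settings and the array build are not given in the sources used here. Each array's median over all 22810 probe sets was exactly 50, so the arrays carry a common scale but not a common spread of signals. The sources give no detection calls and no scan batch.

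Probe sets were named from the platform annotation provided with the series. Symbols were updated by Entrez gene identifier through a RefSeq gene table of the TAIR10.1 assembly. Of 22746 probe sets other than 64 AFFX controls, 13513 had 1 gene, 503 had several and 8730 were not listed. Of those with 1 gene, 13436 matched the gene table. Probe sets with several genes or none listed were tested but never named. Of the 419 genes in the lists fixed beforehand, 66 had a listed probe set and 49 were bright enough to test. Those tested were 3 of 22 auxin response genes, 2 of 25 mitotic cell cycle genes and 8 of 40 photosynthesis genes, for example. Results for a list hold for its tested members only. None of the 8 CIN-TCP genes, the class of TCP transcription factors that the study altered, had a listed probe set. Their signals are therefore not analysed here, and the group labels could not be checked by the level of the targeted genes.

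Values were transformed as log2(value + 16), AFFX controls were removed, and probe sets whose mean over all arrays lay at or above the 40th percentile were kept, which left 13648. All 10 arrays entered 1 linear model with a term for each group (limma 3.58.1 in R 4.3.3, lmFit, contrasts.fit and eBayes with an intensity trend), with 5 residual degrees of freedom shared by the groups. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05, adjusted over all probe sets of that contrast. Every p-value of a probe set is from this limma model. Fold changes are on the log2(value + 16) scale, which understates the change of dim probe sets. Errors of log2 changes are standard errors and errors of signals are standard deviations over 2 arrays. The number of arrays limits the precision, and the median standard error of a difference between groups was 0.17 on the log2 scale. The model gives all groups the same spread, so this value was the same for every pair of groups. Replicates differed more in BLS>>TCP4 (standard deviation of the log2 difference 0.44) than in the other groups (0.24 to 0.30). Errors and p-values may therefore be too small for BLS>>TCP4 and too large for the other groups. The labels do not say that samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

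The 7 contrasts compared miR-3TCP, miR319b, octa and BLS>>TCP4 each with Col, octa with miR319b and with miR-3TCP, and the effect of miR-3TCP with and without miR319b, here called the interaction. Log2 changes were correlated across probe sets for 3 pairs of contrasts that share no array. For pairs that share the Col arrays, 100 simulations of unchanged groups against those arrays gave the value that sharing alone produces. Of 29 gene lists fixed beforehand, 8 had at least 3 members tested and were compared with all other probe sets by limma's camera with a preset inter-gene correlation of 0.01, adjusted over lists and contrasts. A further 25 lists were made after the data had been seen, from ribosomal protein, photosynthesis, histone and plastid-encoded genes and from symbol families of at least 10 probe sets, and were adjusted among themselves. Every camera call lost significance when the inter-gene correlation was estimated from the data. The median of a list was also placed among 10000 random lists of the same size matched on mean signal.

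The genes named were set by a rule. This rule, the gene lists, the contrasts and the alternatives not said to be added were chosen before the data were examined. The rule took the CIN-TCP genes, then for each contrast with Col the 10 largest rises and the 10 largest falls among probe sets with 1 gene that were called and did not overlap between groups, then 5 of each for the other contrasts. It also took up to 4 called members of each gene list, or the 2 of smallest p where none was called. The same was done for the lists added later.

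The model and the list test were tested on simulated data. Each probe set was drawn around its mean over all 10 arrays with the model's shared spread. The simulated groups thus differed only by the changes put in, and no group was noisier than the others. For the model, 200 probe sets were changed in each of 5 runs over 13648 probe sets. For miR-3TCP against Col, 81.2% of changes of 1 on the log2 scale and 99.6% of changes of 2 were called, and 6.32% of calls were false. For octa against Col the shares were 83.4% and 100%, with 3.98% false, and for octa against miR319b they were 83.6% and 99.6%, with 5.86% false. For the interaction they were 40.2% and 97%, with 5.64% false. Where fewer than 200 probe sets change the adjustment is stricter, so these shares do not carry over to contrasts with few calls. Between miR-3TCP and Col, for example, AT3G55920 had a log2 change of 1.51 and was not called. Of 20 lists of 20 probe sets shifted by 0.5, 20 were called, and of 560 unshifted lists 0 were called by camera. The simulated noise was independent between probe sets, so these lists had no inter-gene correlation. The counts therefore do not show how often camera calls unshifted lists of correlated genes.

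Alternatives fixed beforehand were pseudocounts of 1 and 64, no filter or one at the 60th percentile, quantile normalization, centring each array on the median of the kept probe sets, no intensity trend, a fit of only the arrays compared, the replicate number as a block, each array left out in turn, and a minimum log2 change of 1. Alternatives chosen after seeing the data were a fit without the BLS>>TCP4 arrays, limma's array weights (with statmod 1.5.0) and, for BLS>>TCP4, only probe sets with a mean signal of at least 100 in both groups.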

Results

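CIN-TCP genes encode transcription factors that limit growth at leaf margins. The series altered their activity in Arabidopsis thaliana and measured transcripts of the vegetative apex, with 2 arrays in each of 5 groups. Col was the unaltered accession, sampled at 14 DAS, the age code used in the labels. The miR-3TCP plants overexpressed an artificial microRNA against TCP5, TCP13 and TCP17 and were also sampled at 14 DAS. The miR319b plants overexpressed the natural microRNA against TCP2, TCP3, TCP4, TCP10 and TCP24 and were sampled at 17 DAS. The octa plants, sampled at 18 DAS, were taken to be the design's combination of both microRNAs, which targets all 8 CIN-TCP genes. BLS>>TCP4 plants expressed TCP4 from the leaf-specific BLS promoter and were sampled at 14 DAS, in the Ler accession and not in Col. None of the 8 CIN-TCP genes had a named probe set, so the altered genes themselves are not analysed here.

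Signals had a median of 50 on every array. Mean signals lay between 141 and 156 on the 8 arrays of the Col accession and were 191 and 198 on the BLS>>TCP4 arrays, whose brightest probe sets reached 9485 and 9745 against 3816 to 5073 elsewhere. The 99th percentile was 2699 and 2812 on the BLS>>TCP4 arrays and 1554 to 1929 on the others. Replicates correlated at r = 0.979 in Col, 0.983 in miR-3TCP, 0.97 in miR319b, 0.977 in octa and 0.954 in BLS>>TCP4, across probe sets, which are not independent replicates. The standard deviation of the log2 difference between replicates was 0.44 in BLS>>TCP4 and 0.24 to 0.30 in the other groups. Correlations between miR-3TCP and Col arrays ranged from 0.970 to 0.985, against 0.954 to 0.983 between replicates.

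Loss of TCP5, TCP13 and TCP17 activity was addressed by comparing miR-3TCP with Col at the same age. QQS (AT3G30720), an orphan gene whose product affects leaf starch, fell from a signal of 741 ± 90.6 in Col to 4.6 ± 4.49 (SD, n = 2) in miR-3TCP. Its log2 change was -5.21 ± 0.19 (SE), with an adjusted p of 1.39e-06, and it was the only one of 13648 probe sets called. The cyclophilin gene AT3G55920 had signals of 28.2 ± 3.2 in Col and 110 ± 0.755 in miR-3TCP (log2 change 1.51, adjusted p = 0.0761), and the defensin-like gene AT3G05730 had 645 ± 52.0 and 263 ± 59.8 (log2 change -1.26, adjusted p = 0.296). Neither passed the threshold, and both were chosen after their values were seen. By limma, 397 probe sets had an unadjusted p under 0.05, a smaller share of those tested than the 0.05 expected if none changed. The count was 0 with a pseudocount of 1 and with the filter at the 60th percentile, because QQS then fell below the filter and was not tested.

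None of the 8 gene lists moved as a set between miR-3TCP and Col, the smallest camera p being 0.238 after adjustment, for photosynthesis (median log2 change -0.04 over 8 members). The medians of the flavonoid and anthocyanin genes (0.59, adjusted p = 0.317), of leaf polarity genes (0.06, 0.317) and of stomatal lineage genes (-0.06, 0.543) did not pass the test either. No member of the 8 lists was called over all probe sets or adjusted over the list alone by limma, and the smallest unadjusted p was 0.0489, for the auxin-conjugating enzyme gene WES1 (log2 change -0.52). Of the lists chosen after the data had been seen, cytosolic ribosomal protein genes passed, with a small median of 0.053 and 82 of 104 positive (camera adjusted p = 0.00105, and adjusted p = 0.964 with an estimated correlation). By limma 0 of them were called, over all probe sets or adjusted over the list alone.

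**Figure D1:**
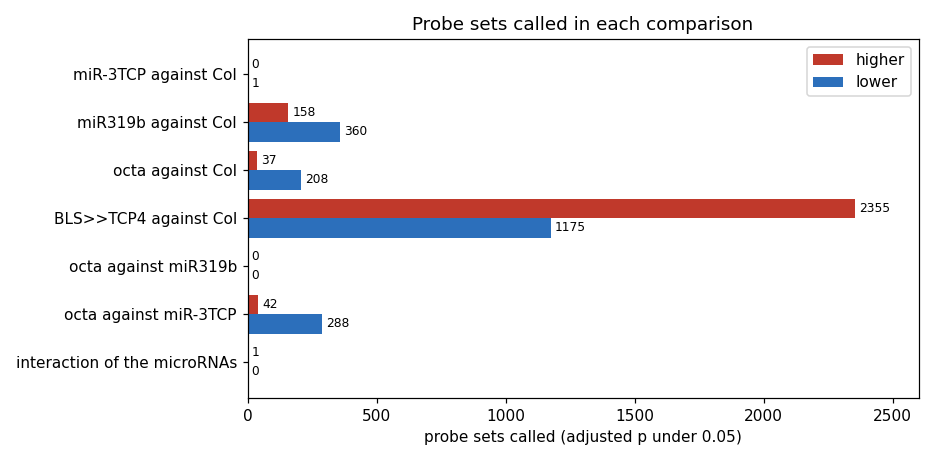
Number of probe sets called higher (red) or lower (blue) in each of the 7 comparisons, at an adjusted p under 0.05 by limma. Counts range from 0 between octa and miR319b to 2355 higher and 1175 lower between BLS>>TCP4 and Col.

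Loss of the miR319 targets was addressed by comparing miR319b with Col. Of 25 genes in the mitotic cell cycle list 2 were tested, both of Aurora kinases, and both fell, also 2 adjusted over the list alone. AUR1 went from 380 ± 49.3 to 172 ± 17.9 (log2 change -1.07 ± 0.17, adjusted p = 0.0167), and AUR2 from 247 ± 2.75 to 113 ± 4.47 (-1.03 ± 0.13, adjusted p = 0.00727). Among called probe sets with 1 listed gene, to which all rankings here are limited, the largest falls after QQS (-4.35 ± 0.19) were AT3G05730 at -3.55 ± 0.19 (40.7 ± 9.04 in miR319b, adjusted p = 3.47e-05) and the tropinone reductase-like gene AT2G29290 at -2.30 ± 0.22 (107 ± 36.4 to 8.36 ± 0.0750). Among the next were the TRAF-like gene AT3G28220 (-1.87) and the thionin gene AT1G66100 (-1.81). Among the largest rises were the metallothionein gene MT1C, from 245 ± 10.2 to 1046 ± 168 (2.02 ± 0.33, adjusted p = 0.0171), AT3G55920 (1.65), the IRON MAN peptide gene AT1G47400 of the iron deficiency response (1.64) and ROXY1, a glutaredoxin gene of floral organ initiation (1.43). In all, 158 probe sets rose and 360 fell.

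Of the 8 gene lists, that of cytosolic ribosome and nucleolus genes was higher in miR319b as a set (median log2 change 0.30 over 5 members, adjusted p = 0.0171). That call was lost with an estimated correlation (adjusted p = 0.334 with an estimated correlation) and with quantile normalization (adjusted p = 0.154). None of its members was called over all probe sets by limma, and 4 were higher adjusted over the list alone. Photosynthesis (median -0.10, adjusted p = 0.431, and a median of -0.28 with quantile normalization), auxin response (0.60, 0.234), leaf polarity (0.40, 0.0803) and the expansins (median -0.13, adjusted p = 0.899) did not pass. Over all probe sets 0 members of these lists were called by limma, against 0, 2, 2 and 1 adjusted over the list alone, all higher. EXPA15, a wall-loosening expansin gene, had signals of 319 ± 83.3 in Col and 793 ± 225 in miR319b (1.27 ± 0.31, adjusted p = 0.055). The cytokinin response regulator gene RR16 had 47.8 ± 18 and 15.2 ± 0.196 (-1.0 ± 0.30, adjusted p = 0.0933), lower adjusted over the list alone as 1 of 2 cytokinin genes.

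In lists chosen after the data had been seen, 2 lists of nuclear genes for plastid functions were lower and cytosolic ribosomal protein genes were higher. Of 10 plastid ribosomal protein genes, 4 were called, all lower, and the median was -0.52, with AT4G17560 falling from 1248 ± 83.9 to 556 ± 68.3 (-1.15 ± 0.14). Of 19 genes of photosynthesis, chlorophyll synthesis and the Calvin cycle, 5 were called, all lower (median -0.34), among them HEME1, HEME2, HEMB1 and CHLI2, which encode tetrapyrrole and chlorophyll synthesis enzymes (-1.21, -0.83, -0.69 and -0.97). Of 104 cytosolic ribosomal protein genes, 7 were called, all higher, and 102 had a positive change, with a median of 0.30. Camera gave adjusted p = 2.66e-05, 4e-05 and 1.75e-18 for these lists, and adjusted p = 0.800, 0.922 and 0.753 with an estimated correlation. The counts between miR319b and Col rested on all 4 arrays, being 19 without Col replicate 1, 7 without Col replicate 2, 57 without miR319b replicate 1 and 14 without miR319b replicate 2. The groups differed in age by label, 17 against 14 DAS, so age and genotype cannot be told apart.

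**Figure D2:**
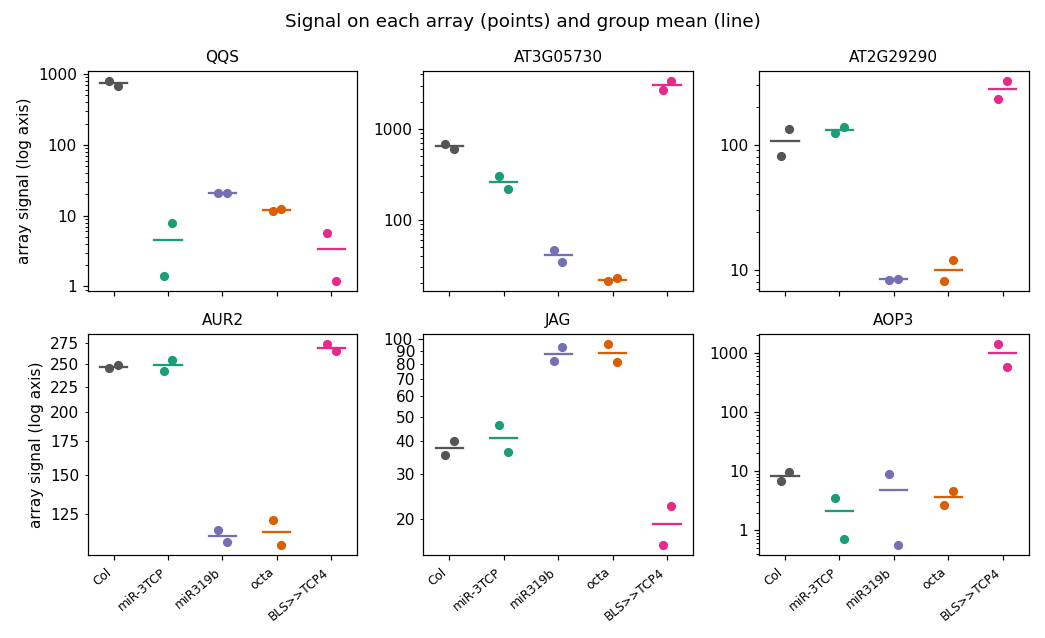
Signal of 6 genes on each of the 10 arrays (points, log axis) with the mean of each group (line). QQS is far lower in all 4 altered groups than in Col (741), AT3G05730 and AT2G29290 are lower in miR319b and octa and higher in BLS>>TCP4, AUR2 is lower in miR319b (113) and octa (115) than in Col (247), JAG, chosen for miR319b after its values were seen, is higher in miR319b and octa and lower in BLS>>TCP4, and AOP3 is at 980 in BLS>>TCP4 against 8.30 in Col.

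Loss of all 8 CIN-TCP genes was addressed by comparing octa with Col. The Aurora kinase genes were lower, both also adjusted over the list alone, AUR1 at 200 ± 6.89 (log2 change -0.87 ± 0.17, adjusted p = 0.0423) and AUR2 at 115 ± 9.16 (-1.01 ± 0.13, adjusted p = 0.0132). JAG, a zinc finger gene that promotes lateral organ growth, rose from 37.8 ± 3.2 to 88.6 ± 9.66 (0.96 ± 0.16, adjusted p = 0.0261), and ROXY1 rose by 0.96. After QQS (-4.75), the largest falls among probe sets with 1 listed gene were AT3G05730 at -4.12 ± 0.19 (21.9 ± 1.26 in octa, adjusted p = 8.21e-06) and AT2G29290 at -2.22 ± 0.22. Among the next were AT1G66100 (-1.60), MAP1C, a gene of organellar methionine aminopeptidase (-1.52), the DNA glycosylase family gene AT5G44680 (-1.50) and the lipid transfer protein-like gene AT5G59330 (-1.48). AT3G55920 (1.35) and AT1G47400 (1.18) led the rises of such probe sets. In all, 37 probe sets rose and 208 fell.

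STOMAGEN, which encodes a secreted peptide that promotes stomata, fell from 204 ± 9.60 to 88.6 ± 9.73 in octa (-1.08 ± 0.22, adjusted p = 0.0446). It was the only one of 3 stomatal lineage genes called, 2 being lower adjusted over the list alone, and the list did not pass (median -0.41, adjusted p = 0.0506). Photosynthesis genes were lower as a set (median -0.30, all 8 negative, adjusted p = 0.00914, but adjusted p = 0.334 with an estimated correlation). Matched random lists had a median of -0.10, and with quantile normalization the list median was -0.16 (adjusted p = 0.0373). Among them only PSBY, a photosystem II subunit gene, was called (-0.47 ± 0.10, adjusted p = 0.0473), and 3 were lower adjusted over the list alone. Auxin response genes (median 0.56, adjusted p = 0.0506) did not pass, with 0 of 3 called by limma and 2 higher adjusted over the list alone.

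Of the lists chosen after the data had been seen, plastid ribosomal protein genes had 4 lower and 0 higher of 10 (median -0.56, camera adjusted p = 2.46e-08), and photosynthesis, chlorophyll and Calvin cycle genes had 3 lower and 0 higher of 19 (median -0.43, adjusted p = 1.09e-09), with CHLI2 at -1.12. Both had adjusted p = 0.648 with an estimated correlation. Medians of matched random lists were -0.13 and -0.11, and the brightest of 5 equal groups of probe sets by mean level had a median of -0.13. The count of 245 was 11 without Col replicate 1, 6 without Col replicate 2, 5 without octa replicate 1 and 7 without octa replicate 2, and was 154 with quantile normalization (49 higher) and 120 with median centring (31 higher). Ages differed, 18 against 14 DAS, so age and genotype cannot be told apart here.

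**Figure D3:**
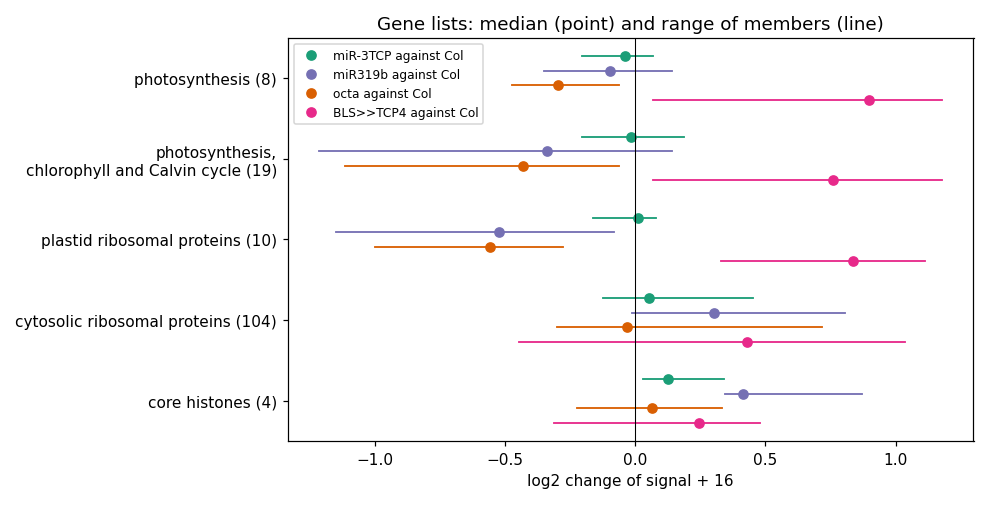
Log2 change of signal + 16 against Col for 5 gene lists, with the number of members tested in brackets. Points are list medians and lines run from the lowest to the highest member. Medians of the photosynthesis, chlorophyll and plastid ribosomal lists lie below 0 in miR319b, where the 8 photosynthesis genes did not pass (adjusted p = 0.431), and in octa, and above 0 in BLS>>TCP4 (median 0.84 for plastid ribosomal proteins), where quantile normalization brings the 3 plastid medians to 0.07, 0.17 and 0.12 and turns the cytosolic ribosomal median to -0.08.

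Gain of TCP4 in leaves was addressed by comparing BLS>>TCP4 with Col. AT3G05730, which was lower in miR319b and octa, rose from 645 ± 52.0 to 3050 ± 492, and STOMAGEN rose from 204 ± 9.60 to 537 ± 208 (log2 change 1.28 ± 0.22, adjusted p = 0.00289). The stomatal lineage list did not pass (median 0.06, camera adjusted p = 0.899). Of its 3 members tested, 1 was higher and 1 lower adjusted over the list alone. The largest rise among probe sets with 1 listed gene was AOP3, a glucosinolate side-chain gene known to be active in Ler and not in Col, from 8.30 ± 2.03 to 980 ± 579 (5.23 ± 0.35, adjusted p = 1.95e-05), and among the next were AT5G15360 (3.56), the plastid gene ndhC (2.81), the cyclophilin gene AT2G21130 (2.73), MT1C (2.64) and AT1G13650 (2.59). Among the largest falls were QQS (-5.29 ± 0.19), AT2G33850, from 873 ± 191 to 6.75 ± 4.77 (-5.29 ± 0.24), ZW9 (-4.91), ECS1 (-4.35) and AT2G25450, a dioxygenase gene of glucosinolate side chains (-4.10). In all, 2355 probe sets rose and 1175 fell, 25.9% of those tested.

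Photosynthesis genes were higher in BLS>>TCP4 as a set, with 7 of 8 called higher, also 7 adjusted over the list alone (median 0.90, adjusted p = 0.000158). That set call was lost with an estimated correlation (adjusted p = 0.334 with an estimated correlation) and with quantile normalization (median 0.07, adjusted p = 0.72). RCA, the Rubisco activase gene, went from 2946 ± 64.2 to 6143 ± 188 (1.06 ± 0.08), and PSBY, PSAE-1 and PSAN of the photosystems rose by 1.18, 1.05 and 1.04. Random lists matched on mean signal had a median of 0.69, and the list lay at percentile 96.5 of them. Auxin response genes were lower as a set (median -0.68, adjusted p = 0.042, and adjusted p = 0.334 with an estimated correlation), with 2 of 3 called lower, also 2 adjusted over the list alone. These were GH3.3, an auxin-conjugating enzyme gene, from 228 ± 22.8 to 89.9 ± 28.6 (-1.23 ± 0.21, adjusted p = 0.00274), and IAA30 (-0.68 ± 0.19, adjusted p = 0.0276). With the replicate number as a block the list had adjusted p = 0.0534.

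Cytosolic ribosome and nucleolus genes had 4 of 5 called higher, also 4 adjusted over the list alone, but the list did not pass (median 0.64, adjusted p = 0.068) and its median was -0.02 with quantile normalization and 0.64 in matched random lists. The gibberellin receptor genes GID1B and GID1A fell (-0.79 and -0.56), 2 of 3 also adjusted over the list alone (list median -0.56, adjusted p = 0.196). Of 3 flavonoid and anthocyanin genes AT4G14090, an anthocyanin glucosyltransferase gene, rose (2.27 ± 0.66, adjusted p = 0.0309), 1 also adjusted over the list alone (list median 0.91, adjusted p = 0.484). Among 2 cytokinin response genes RR16 rose (1.52 ± 0.30) and ARR15 fell (-0.85 ± 0.19). Single members of lists too small to test as sets also changed, with falls of TCP15, a TCP gene of another class (-0.60), of the jasmonate synthesis gene OPCL1 (-1.23), of the flowering gene AGL24 (-0.70) and of PYK10, a root marker (-0.63), and a rise of the trichome regulator gene GIS (0.74). SIM, the other of 2 trichome genes tested, had -0.64. It was lower adjusted over the list alone but not called over all probe sets. In the lists added later, 8 of 10 plastid ribosomal protein genes (median 0.84), 14 of 19 photosynthesis, chlorophyll and Calvin cycle genes (0.76) and 55 of 104 cytosolic ribosomal protein genes (0.43) rose. With quantile normalization these medians were 0.12, 0.17 and -0.08, and the set calls were lost (adjusted p = 0.386, 0.386 and 0.22). Matched random lists had medians of 0.58, 0.55 and 0.52, the last above that of the cytosolic list, which lay at percentile 4.91. Camera gave these lists adjusted p = 9.73e-05, 3.23e-07 and 3.56e-10, and adjusted p = 0.902, 0.753 and 0.964 with an estimated correlation.

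The count of 3530 calls in BLS>>TCP4 was 2536 with quantile normalization (1217 higher and 1319 lower), 1755 with only these 4 arrays fitted, 1649 without Col replicate 1 and 1978 without Col replicate 2. The groups differed in accession, Ler against Col, so the accession and the transgene cannot be told apart.

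Adding miR-3TCP to miR319b was addressed by comparing octa with miR319b, and no single gene passed the test. AUR1 and AUR2, lower than Col in both groups, had log2 differences of 0.20 ± 0.17 and 0.02 ± 0.13 between them. Cytosolic ribosome and nucleolus genes were lower in octa as a set (median -0.30, adjusted p = 0.0171, and adjusted p = 0.334 with an estimated correlation), with 3 lower adjusted over the list alone, and with quantile normalization the list had a median of -0.07 (adjusted p = 0.741). Photosynthesis genes had a median of -0.16 (adjusted p = 0.0414, and adjusted p = 0.499 with an estimated correlation) with 1 lower adjusted over the list alone, and the median turned to 0.14 with quantile normalization. Matched random lists had a lower median, -0.26, and the list lay at percentile 92.8 of them. Of the lists added later, 100 of 104 cytosolic ribosomal protein genes had a negative difference (median -0.33, adjusted p = 2.04e-24), where matched random lists had a median of -0.20 and quantile normalization brought the list to -0.10 (adjusted p = 0.000235). The 4 core histone genes tested, HTB1, HTB2, HTB4 and HTB11, all encode histone H2B. They had a median of -0.46 (camera adjusted p = 0.00836). Both lists had adjusted p = 0.648 with an estimated correlation. By limma 0 probe sets were called and 1342 had an unadjusted p under 0.05, a larger share of those tested than the 0.05 expected if none changed. Ages were 18 and 17 DAS.

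Adding miR319b to miR-3TCP was addressed by comparing octa with miR-3TCP. The largest falls among probe sets with 1 listed gene had log2 changes of -2.86 ± 0.19 for AT3G05730 and -2.5 ± 0.22 for AT2G29290, followed by AT1G11850 (-1.71), AT1G13650 (-1.57) and AT3G57160 (-1.51). AUR1 (-0.96 ± 0.17, adjusted p = 0.0265), AUR2 (-1.02 ± 0.13, adjusted p = 0.0119) and STOMAGEN (-1.02 ± 0.22, adjusted p = 0.0433) fell, and AT1G20070 (1.79) and AT1G29270 (1.16 ± 0.13, adjusted p = 0.00857) rose. The 3 of 22 auxin response genes tested were higher in octa as a set (median 0.53, camera adjusted p = 0.0124). With an estimated correlation camera gave adjusted p = 0.334. None of the 3 was called over all probe sets by limma, and 3 were higher adjusted over the list alone. Photosynthesis genes were lower (median -0.20, adjusted p = 0.042), with 1 of 8 called lower, PSAE-1 at -0.45, also 1 adjusted over the list alone. That call was lost with an estimated correlation (adjusted p = 0.499 with an estimated correlation), with quantile normalization (median -0.10, adjusted p = 0.264) and with the replicate number as a block (adjusted p = 0.0531).

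Of the lists added later, 5 of 10 plastid ribosomal protein genes were lower in octa than in miR-3TCP (median -0.57, adjusted p = 5.93e-09, and adjusted p = 0.648 with an estimated correlation), as were 6 of 19 photosynthesis, chlorophyll and Calvin cycle genes (median -0.42, adjusted p = 2.35e-08, and adjusted p = 0.679 with an estimated correlation), CHLI2 at -1.30 and HEME1 at -1.0. With quantile normalization the median of the latter list was -0.27 (adjusted p = 1.86e-06). In all, 42 probe sets rose and 288 fell between miR-3TCP and octa. That count of 330 was 19 without miR-3TCP replicate 1, 8 without miR-3TCP replicate 2, 9 without octa replicate 1 and 6 without octa replicate 2. With quantile normalization 71 rose and 222 fell, and ages were 18 and 14 DAS.

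Whether miR-3TCP acted differently with and without miR319b was tested as an interaction. QQS was the only call, at 4.81 ± 0.27 (adjusted p = 8.75e-05), being -5.21 between miR-3TCP and Col and 12.0 ± 0.591 in octa against 21.0 ± 0.188 in miR319b. Its signal was already near the floor in miR319b, on arrays where 33.0% to 34.2% of probe sets lay below 16. It could hardly fall further there, so this call restates the difference from Col and does not show that miR-3TCP acted differently. Cytosolic ribosome and nucleolus genes had a negative interaction as a set (median -0.36, all 5 negative, adjusted p = 0.0124, and adjusted p = 0.334 with an estimated correlation). With quantile normalization this median was -0.10 (adjusted p = 0.344), and 0 of 5 members were called by limma, over all probe sets or adjusted over the list alone. Without an array in turn 1 or 2 probe sets were called, the 2 without octa replicate 1, and 974 had an unadjusted p under 0.05. The count was 0 where QQS fell below the filter, with a pseudocount of 1 and with the filter at the 60th percentile.

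The effect of miR319b was compared without and with miR-3TCP. Across 13648 probe sets, which are not independent replicates, the change from Col to miR319b correlated with that from miR-3TCP to octa at r = 0.532 (Spearman's rho 0.43), and the 4 groups shared no array between the changes. Of the calls, 149 were lower in both comparisons and 17 were higher in both, against 7.60 and 0.486 for independent lists, and 0 were opposite. Both changes also ran from 14 DAS to a later age, 17 DAS in miR319b and 18 DAS in octa. A shared effect of age therefore cannot be told apart from that of miR319b. The effect of miR-3TCP without miR319b did not correlate with that in its presence (r = -0.031, rho -0.07), and r took either sign when 1 array was left out (0.080 without Col replicate 2, 0.059 without miR-3TCP replicate 1, 0.0074 without miR319b replicate 2 and 0.127 without octa replicate 2). With the Col arrays shared, miR319b and octa correlated at r = 0.740 where simulated unchanged groups gave 0.50. The covariance was 0.085 against a simulated 0.019.

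The change from Col to BLS>>TCP4, which also differ in accession, was compared with that from miR-3TCP to octa, which also differ in age. Of 330 probe sets called between octa and miR-3TCP, 268 (81.2%) had the opposite sign between BLS>>TCP4 and Col, against 58.2% of all probe sets tested. Unequal signal distributions can add to this. The brightest of 5 equal groups of probe sets by mean level had a median of 0.30 between BLS>>TCP4 and Col and -0.12 between miR-3TCP and octa. With quantile normalization 214 of 293 (73.0%) were opposite, against 56.8% of all tested. The other values of this paragraph are without it. Called in both, 164 were higher with TCP4 and lower in octa, where independent lists would share 49.7, and 20 were lower with TCP4 and higher in octa (3.62), whereas 4 were higher in both (7.25) and 13 lower in both (24.8). The 72 named genes among the opposite ones included AT3G05730, AT1G13650, STOMAGEN and, in the other direction, JAG and AT1G29270. Over all probe sets r was -0.199 (rho -0.22), and from -0.254 to -0.109 with 1 array left out. The changes of octa and of BLS>>TCP4 against the shared Col arrays had r = -0.011 where unchanged groups gave 0.50. Their covariance differed from the simulated one by -0.0213.

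**Figure D4:**
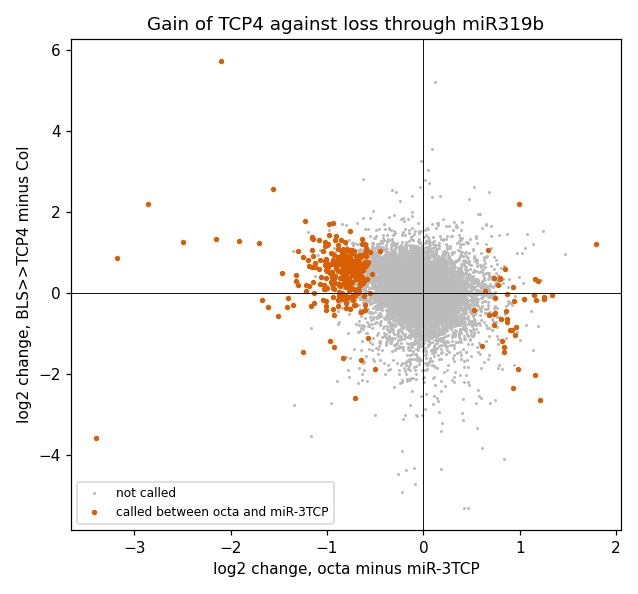
Log2 change between BLS>>TCP4 and Col (y axis) against that between octa and miR-3TCP (x axis) for 13648 probe sets, with those called between octa and miR-3TCP in orange. Of the 330 called, 268 lie on opposite sides of 0 on the 2 axes, most of them at the upper left. The values shown are without quantile normalization, with which 214 of 293 called were opposite.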

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

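The tests below were chosen after the results were seen, except those of the chromosome stretch around QQS and of single arrays in the ribosomal list, which were set before their outcome was known.

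QQS met the test of a difference between groups, with an interaction of 4.81 on the log2 scale between the effect of miR-3TCP without and with miR319b, since it was high in Col and low in all 4 other groups, so near the floor in miR319b that this does not show a different effect of miR-3TCP. A general difference of the Col arrays by 2 or more on the log2 scale over many probe sets is argued against. Between miR-3TCP and Col 0 others changed by that much. This cutoff does not bear on smaller differences. A difference of the Col samples at a few loci stays open. With QQS, 5 probe sets had log2 changes of at least 1 in the same direction in all 4 comparisons with Col, though QQS alone was called in miR-3TCP. Lower CIN-TCP activity cannot be told apart from other causes, as QQS was also lower by -5.29 where TCP4 was gained, but that group is of another accession. A lowered chromosome stretch stays open too: the 10 nearest genes tested had a median change of 0.0013, but in the gene order of the TAIR10.1 assembly the nearest lay 81 genes before and 146 genes after QQS, too far to bear on it. Heritable DNA methylation states, for which QQS is known among Arabidopsis lines, could be a source of the difference, and methylation was not analysed here.

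Between BLS>>TCP4 and Col, far more probe sets were called than in any other comparison. The wider signal distribution of the BLS>>TCP4 arrays is argued against as the whole cause, since 2536 probe sets were still called after quantile normalization, where the next highest comparison had 579. The spread shared by all groups, which may be too small for BLS>>TCP4 and too large for the others, can add to this gap. Without quantile normalization, BLS>>TCP4 and miR319b against Col had 1755 and 509 calls with only the arrays compared. With array weights they had 2055 and 1114. Both causes together were not tested. Sequence differences of Ler under the probes lower signals and are argued against for the rises, 229 of which reached 1 on the log2 scale after quantile normalization against at most 128 calls of that size elsewhere. For the 1319 falls under that setting such differences cannot be told apart from the transgene, because no other Ler array was analysed. Leaf-specific TCP4 may account for probe sets that also changed between octa and miR-3TCP, of which 73.0% (214 of 293) had the opposite sign after quantile normalization, against 56.8% of all tested, while the accession remains an open explanation for all of these calls.

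The remaining results were 3 gene lists that showed an interaction between the microRNAs. They were cytosolic ribosome and nucleolus genes (median -0.36), cytosolic ribosomal protein genes (-0.38, from a list added later) and core histone genes (-0.56, also added later). The core histone genes tested were all of histone H2B. The first list also holds genes of cytosolic ribosomal proteins, so it is not independent of the second. All 3 lists were higher in miR319b than in Col and lower in octa than in miR319b. Those comparisons share the miR319b arrays, so the directions are not independent of each other. All calls were lost with an estimated inter-gene correlation (interaction camera adjusted p = 0.334, 0.648 and 0.648). The first was also lost with quantile normalization (median -0.10, camera adjusted p = 0.344) and lay at percentile 11.3 of matched lists without it. For cytosolic ribosomal proteins, unequal signal distributions are argued against as the whole cause, because the median was still -0.18 after quantile normalization, where that of all probe sets was -0.0044; without it, the list had -0.38 and matched random lists -0.20. A single array is argued against as the whole source of the negative median. Without quantile normalization the median stayed at or below -0.29 without each array in turn. It was -0.29 without miR319b replicate 2 and -0.48 without miR319b replicate 1. Matched lists were not redrawn without each array, so this cannot decide whether 1 array made the excess over them. Age at harvest cannot be told apart from genotype, since the list differed by -0.33 between octa at 18 DAS and miR319b at 17 DAS and each genotype had 1 age. An effect of combining the microRNAs stays open as a hypothesis.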

How the results depend on the processing

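The fit without the BLS>>TCP4 arrays, array weights and the signal minimum were settings chosen after the data had been seen. The cause of a change was not tested unless stated. Counts in the order miR319b against Col, octa against Col and octa against miR-3TCP were 518, 245 and 330. They were 238, 74 and 84 with no filter, 129, 66 and 75 with a minimum log2 change of 1, 1332, 557 and 592 without the BLS>>TCP4 arrays, and 1114, 676 and 911 with array weights, which gave the BLS>>TCP4 arrays 0.405 and the others 0.996 to 1.65. For octa against Col the count was 155 with no intensity trend, 154 with quantile normalization and 120 with median centring. The higher share there was 15.1%, 31.8% with quantile normalization and 25.8% with median centring, and for octa against miR-3TCP it was 12.7% and 24.2% with quantile normalization. For BLS>>TCP4, 3530 calls (66.7% higher) became 1755 with only the arrays compared, 886 with a minimum log2 change of 1, 2055 with array weights and 2110 with the signal minimum of 100. The higher share there was 48.0% with quantile normalization, 49.7% with the minimum log2 change and 80.4% with the signal minimum. The calls between miR-3TCP and Col were 0 with a pseudocount of 1 or the filter at the 60th percentile and 2 with array weights, and those of the interaction 0, 0 and 2, with 1 of each 2 higher. Between octa and miR319b 2 were called with a pseudocount of 1, the filter at the 60th percentile or quantile normalization, 1 without the BLS>>TCP4 arrays and 3 with array weights. All other settings left these 7 counts within 1.5 times.

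With each array left out in turn, the lone array is assumed to vary like the other groups. Counts then ranged from 1 to 1 for miR-3TCP, 7 to 57 for miR319b, 5 to 11 for octa, 1649 to 3807 for BLS>>TCP4, 0 to 0 for octa against miR319b, 6 to 19 for octa against miR-3TCP and 1 to 2 for the interaction (2 without octa replicate 1). The share called higher moved by over 10 points for miR319b without Col replicate 1 (2 of 19) or 2 (0 of 7), for octa without Col replicate 1 (0 of 11) or 2 (0 of 6) or octa replicate 1 (0 of 5), and for octa against miR-3TCP without miR-3TCP replicate 1 (0 of 19) or octa replicate 1 (0 of 9) or 2 (0 of 6). The correlation of the miR319b effects ranged from 0.345 to 0.618, that of gain and loss from -0.254 to -0.109, and that of the miR-3TCP effects from -0.156 to 0.127, turning positive without Col replicate 2 (0.080), miR-3TCP replicate 1 (0.059), miR319b replicate 2 (0.0074) or octa replicate 2 (0.127). Of 142 pairings of a named gene with a comparison, 4 reversed, all in BLS>>TCP4 with quantile normalization: AT3G09630 (-0.021), AT5G02870 in BLS>>TCP4 against Col (-0.0097), AT2G19730 (-0.25) and AT2G34480 (-0.066), genes of cytosolic ribosomal proteins. Lists reversed under the same setting were photosynthesis between octa and miR319b (0.14) and cytosolic ribosomal proteins in BLS>>TCP4 (-0.077). No filter ended 49 of the 142 calls, quantile normalization 23 of 141 and the replicate number as a block 9 of 142. Leaving out replicate 1 or 2 ended 68 and 66 of 120 for Col, 17 and 19 of 24 for miR-3TCP, 26 and 31 of 36 for miR319b, 46 and 45 of 53 for octa, and 4 and 1 of 53 for BLS>>TCP4. Signal over background limits dim probe sets, and 30.6% to 34.2% of probe sets on an array lay below 16.

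The labels of same-numbered samples share only a number. Deviations of same-numbered arrays correlated at -0.40 to 0.45 over 10 pairs of groups, 3 of them over 0.1. Negative values included -0.40 for miR319b with octa and -0.20 for Col with miR319b. The numbers may be arbitrary, so a value of either sign could come from a shared source. A shared batch is neither shown nor excluded by these values. With the replicate number as a block the counts were 1, 535, 236, 3584, 0, 333 and 1 for miR-3TCP, miR319b, octa and BLS>>TCP4 against Col, octa against miR319b, octa against miR-3TCP and the interaction.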

Other observations

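The tests and values of this part were all chosen after the data had been seen.

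The list of plastid-encoded genes did not pass camera in any comparison. Of 16 such genes bright enough to test, psbA alone was called in miR319b, from a signal of 45.3 ± 8.14 in Col to 89.8 ± 23.0 (log2 change 0.78 ± 0.18, adjusted p = 0.0477), and the list's median was -0.10 (camera adjusted p = 0.756). In octa 0 of the 16 were called by limma, psbA being at 53.9 ± 6.72, and the median was -0.05 (adjusted p = 0.97). In BLS>>TCP4 4 were called, all higher, namely ndhC (2.81 ± 0.33), rpoA (1.53 ± 0.21), psbF (0.83 ± 0.16) and psbZ (0.58 ± 0.14), with a list median of 0.18 (adjusted p = 0.34). Changes were negative for 11 of the 16 in miR319b and 10 in octa and positive for 14 in BLS>>TCP4, and the difference from the nuclear lists was not tested. Mean signals of the 16 in Col ran only from 24.3 (psbZ) to 69.7 (rpoA), where each array's median was 50. Such signals may lie close to background and need not measure the levels of plastid transcripts.

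Of symbol families with at least 10 probe sets, 1 passed camera, that of symbols starting with GH. Of its 8 members tested, 4 were called lower in BLS>>TCP4, the auxin-conjugating enzyme genes GH3.3 (-1.23) and GH3.17 (-1.04) and the glycosyl hydrolase genes GH9B13 (-0.73) and GH9B7 (-0.56) (list median -0.44, adjusted p = 0.0411), and 7 had a positive change from miR-3TCP to octa (median 0.25, adjusted p = 0.0362). Both calls were lost with an estimated correlation (adjusted p = 0.648 with an estimated correlation), and the fall in BLS>>TCP4 had adjusted p = 0.0645 with quantile normalization.

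Besides QQS, 4 probe sets had log2 changes of at least 1 in the same direction in all 4 comparisons with Col, and 1 of these has a gene name. None of the 4 was called between miR-3TCP and Col, where QQS was the only call. AT3G55920 had signals of 28.2 ± 3.2 in Col, 110 ± 0.755 in miR-3TCP, 123 ± 12.3 in miR319b, 98.4 ± 29.2 in octa and 141 ± 20.6 in BLS>>TCP4.

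Of the 72 named genes called in opposite directions with TCP4 and in octa, 64 were higher in BLS>>TCP4 and lower in octa than in miR-3TCP. Among these the signal of AT1G13650 was 275 ± 47.0 in BLS>>TCP4, 48.4 ± 26.9 in miR-3TCP and 4.78 ± 0.0345 in octa, and that of AT1G11850 was 336 ± 8.23, 160 ± 45.3 and 36.8 ± 1.61. The other 8 ran the other way, among them AT1G29270, at 20.4 ± 2.37 in BLS>>TCP4, 127 ± 11.4 in miR-3TCP and 303 ± 20.6 in octa.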
